A study of Mus musculus with 48 samples.

How the data were processed

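The data are 48 mouse RNA sequencing libraries in 15 groups. Per the submitters' processing notes, reads were quantified with Salmon against mm10, and the versions of both are not given in the sources used here. The annotation release, the read trimming, any filter on transcripts and the strand setting are also not given in the sources used here. Per the file headers and the values, 1 table holds estimated counts per Ensembl gene, which are not all whole numbers and whose library totals run from 2558141 to 48263706. Per the file headers and the values, the other table holds TPM as deposited, transcript abundances scaled by the submitters so that each library has the same sum. Both tables list 54331 genes, of which 54097 were matched to a symbol, a position and a biotype in GENCODE M21 on GRCm38. Positions in the text are from that annotation.

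The groups follow the titles, sources and characteristics of the samples. EU libraries hold RNA captured by an ethynyl uridine label from the superior colliculus (SC), the lateral geniculate nucleus (LGN) or retinal cells, after injection of the label into the eye. TRAP libraries hold ribosome-bound RNA captured by a tagged ribosomal protein (translating ribosome affinity purification). Replicates are numbered in the order of their title codes, and the digits of the codes served as the block in 1 alternative. The wild-type P14 SC groups hold 5 libraries each, from 2 series of title codes. Replicates 3 to 5 share their code series with the other SC groups and were used in every comparison except that of SC with LGN, which used replicates 1 and 2, the series of the LGN libraries.

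Estimated counts were rounded, genes with low counts were removed with the filterByExpr function of edgeR, and libraries were scaled with TMM factors. Each of 16 comparisons was fitted by itself in edgeR with the quasi-likelihood F test, two-sided, and p-values were adjusted over the tested genes by the method of Benjamini and Hochberg. A gene is called when its adjusted p is under 0.05. A further 3 models tested the difference between 2 comparisons as an interaction: the TRAP to EU ratio at P14 against P10, and the difference of the labelled fmr1ko effect between EU and FACS libraries and between TRAP and EU libraries. Levels are TMM-normalised CPM (counts scaled by library size), given as mean ± SD over libraries, and fold changes are log2 values with ± SE. Tool versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

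For 36 gene lists (cell type markers, complexes, pathways and reported targets of FMRP, the RNA-binding protein encoded by Fmr1), camera compared the members with all other tested genes, with the preset correlation of 0.01 and again with a correlation estimated from the data. A list needed at least 5 tested members. For each list the members called among all genes are given, and those called when p-values were adjusted over the list alone. The genes named in the text follow a rule. It takes the 8 largest rises and the 8 largest falls with adjusted p under 0.05, an absolute log2 fold change of at least 1, an average log2 CPM of at least 4, no overlap between the groups and no predicted gene symbol. It adds the 3 members with the smallest adjusted p of each called list, the 3 members of each marker list with the highest CPM, and Fmr1 and Sarm1 where the genotype changes. Not all genes that it picked are reported here. The groups, comparisons, gene lists, naming rule and most alternatives were chosen before the data were examined. Chosen after seeing the data were the removal of a trend on transcript length, the fit without CT010467.1 (a gene annotated as ribosomal RNA) and the mitochondrially encoded genes, and the closer look at libraries that stood apart.

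Where a group had no counts, the fold is a lower bound, taken against a floor of 3 counts over the summed effective library sizes of that group. Floors cover counting error only, since the reads carry no molecular identifiers. Nothing in the labels says that the libraries of a group come from separate animals, and the EU protocol describes pools of animals, so p-values measure the spread between libraries. Levels of near-identical gene copies, of mitochondrially encoded genes with nuclear copies and of overlapping genes on opposite strands are uncertain because shared reads are divided between them by the quantification.

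Alternatives were RLE size factors, no filter, the DESeq2 Wald test, limma-trend on log2(TPM + 1), all 5 wild-type P14 SC libraries, replicate numbers as a block, other soma groups, each library left out in turn, and those added later. Counts were simulated from 3 of the comparisons with known changes to check the procedure. With edgeR, 0 of 219, 20 of 219 and 64 of 220 changed genes were called, with 0, 2 and 9 false calls. The false share was 84.4%, 35.6% and 30.1% with DESeq2 and 0%, 33.3% and 14.3% with limma-trend. For a list of changed genes camera gave p-values of 0.000044, 6.4e-13 and 3.3e-14 in the right direction. False list calls were not tested. Removal of an imposed length trend lowered its rank correlation from 0.6 to 0.04, 0.76 to 0.02 and 0.8 to 0.03. Sequence reads, isoforms, introns and single transcripts were not analysed.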

Results

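The data are 48 mouse RNA libraries on the axons of retinal ganglion cells (RGC), the neurons that carry visual signals from the eye to the superior colliculus (SC) and the lateral geniculate nucleus (LGN). EU libraries hold RNA captured from the target region or from eye cells after ethynyl uridine, an RNA label, was injected into the eye, and TRAP libraries hold RNA bound to tagged ribosomes. From wild-type SC there were EU libraries at P10 (n = 3), at P14 (n = 5), at 8 weeks (n = 3) and at P10 followed by a 4-day chase (n = 3). TRAP libraries of wild-type SC were at P10 (n = 3) and P14 (n = 5). From LGN at P14 there were 2 EU and 3 TRAP libraries. Libraries with the fmr1ko label were EU (n = 3), TRAP (n = 3) and FACS-sorted eye cells (n = 3), and the sarm1ko EU libraries (n = 3) came from axotomized mice at P14 with a 7-day chase. Eye cells of wild-type mice at P14 were immunopanned RGC (n = 3), immunopanned RGC with EU capture (n = 3) and FACS-sorted cells (n = 3). Library totals ran from 2558141 to 48263706 estimated counts, with a median of 22212787. P14 SC groups in the comparisons are replicates 3 to 5 unless said otherwise, so each group has n = 3 libraries, and levels are normalised CPM, mean ± SD. For each gene that is named with its levels and called among all tested genes in a comparison of 3 with 3 libraries, all 3 libraries of 1 group lay above all 3 of the other.

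Fmr1 (chr X, 68678541 to 68717963) encodes FMRP, an RNA-binding protein that represses translation, and it was not called lower in any comparison of libraries labelled fmr1ko with wild type. In EU libraries Fmr1 had 11.8, 3.11 and 15.7 CPM under the fmr1ko label against 1.37, 1.74 and 0.421 CPM in wild type (log2 fold change 3.07 ± 0.74, adjusted p = 0.069). It was called higher there with no filter (log2 fold change 3.05), DESeq2 (3.05), limma on TPM (2.32) and without P14 EU replicate 5 (2.69). P14 replicates 1 and 2 had 0 and 8.09 CPM. Means of the other wild-type EU groups of SC were 8.22 CPM at P10, 8.32 CPM in the chase and 11.3 CPM at 8 weeks, and the mean under the label was 10.2 CPM. In TRAP libraries it had 0.15, 11 and 2.79 CPM against 2.82, 4.05 and 12.3 CPM (log2 fold change −0.24 ± 1.54, adjusted p = 0.97). The sign turned without fmr1ko replicate 1 (0.29), without fmr1ko replicate 3 (0.06), without P14 TRAP replicate 5 (0.51) and with the length trend removed (0.27). With a replicate block it was −1.79. Without fmr1ko replicate 2 it was −2.29 (adjusted p = 0.36), with both remaining libraries below all 3 of wild type. In FACS libraries it had 26.7, 3.76 and 5.42 CPM against 32.1, 20.7 and 6.81 CPM (log2 fold change −0.62 ± 0.9, adjusted p = 0.89), and the log2 fold change was −1.99 without fmr1ko replicate 1 and −0.08 without wild-type replicate 1. A fall in TRAP and FACS libraries is therefore not excluded. A knockout allele can still give a transcript, so these groups are called libraries labelled fmr1ko throughout. Sarm1 (chr 11, 78472330 to 78497754) encodes an NADase that drives the degeneration of cut axons. It was lower in the sarm1ko libraries, at 3.05 ± 0.376 against 27.2 ± 13 normalised CPM in wild-type P14 EU libraries (log2 fold change −3.15 ± 0.48, adjusted p = 0.0021; n = 3 each). The call ended with all 5 wild-type P14 EU libraries as the control (log2 fold change −2.67). In CPM without TMM scaling, Sarm1 ran from 1.25 to 4.37 in the sarm1ko libraries and from 2.74 to 26.4 in P14 EU replicates 1 and 2. Its lowest values at 8 weeks (3.58 CPM) and in immunopanned RGC without EU capture (3.16 CPM) were as low. Low Sarm1 thus also occurred in some wild-type libraries.

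**Figure D1:**
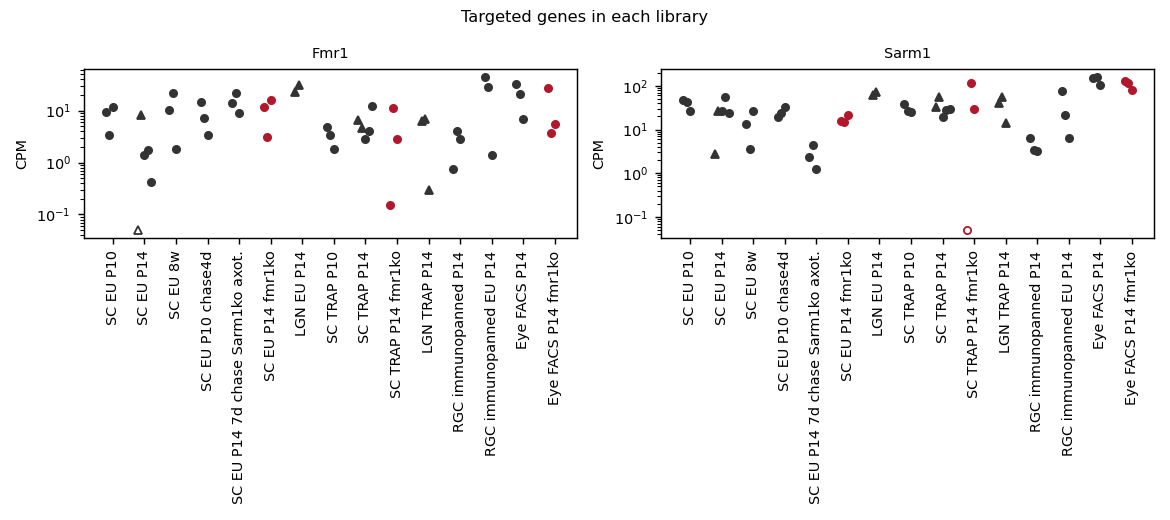
CPM (log axis) of Fmr1 and Sarm1 in each library, with 1 point per library, triangles for the code series of the LGN libraries, red for libraries labelled fmr1ko and open symbols for libraries with no counts. Fmr1 in the EU libraries labelled fmr1ko lies above wild-type P14 replicates 3 to 5, and Sarm1 in the 3 sarm1ko libraries lies between 1.25 and 4.37 CPM. That range also holds the lower of P14 SC EU replicates 1 and 2 (2.74 CPM).

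Markers of other cell types differed between groups. Summed over the rod photoreceptor list, wild-type FACS libraries had 151000 ± 53900 CPM, immunopanned EU libraries 56800 ± 77000 CPM and immunopanned libraries 15700 ± 13500 CPM. P14 SC EU libraries had 21.1 ± 9.15 CPM and P14 SC TRAP libraries 33.4 ± 4.05 CPM (n = 3 each). Oligodendrocyte and myelin markers summed to 13900 ± 3120 CPM in P14 SC EU libraries, 17200 ± 8870 CPM in P14 SC TRAP libraries and 51.3 ± 32 CPM in immunopanned EU libraries. Crystallins took 30.2% and 33% of the counts of immunopanned replicates 2 and 3 and 0.00398% in replicate 1, and mitochondrially encoded genes 47.3% and 42.3% against 0.144%. In the EU libraries of SC, CT010467.1, a gene annotated as ribosomal RNA, took 10.9%, 4.54% and 33.7% of the counts in P14 replicates 3 to 5, 27.9% in P10 replicate 2 and 46.6%, 27.4% and 48.5% in the sarm1ko libraries.

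**Figure D2:**
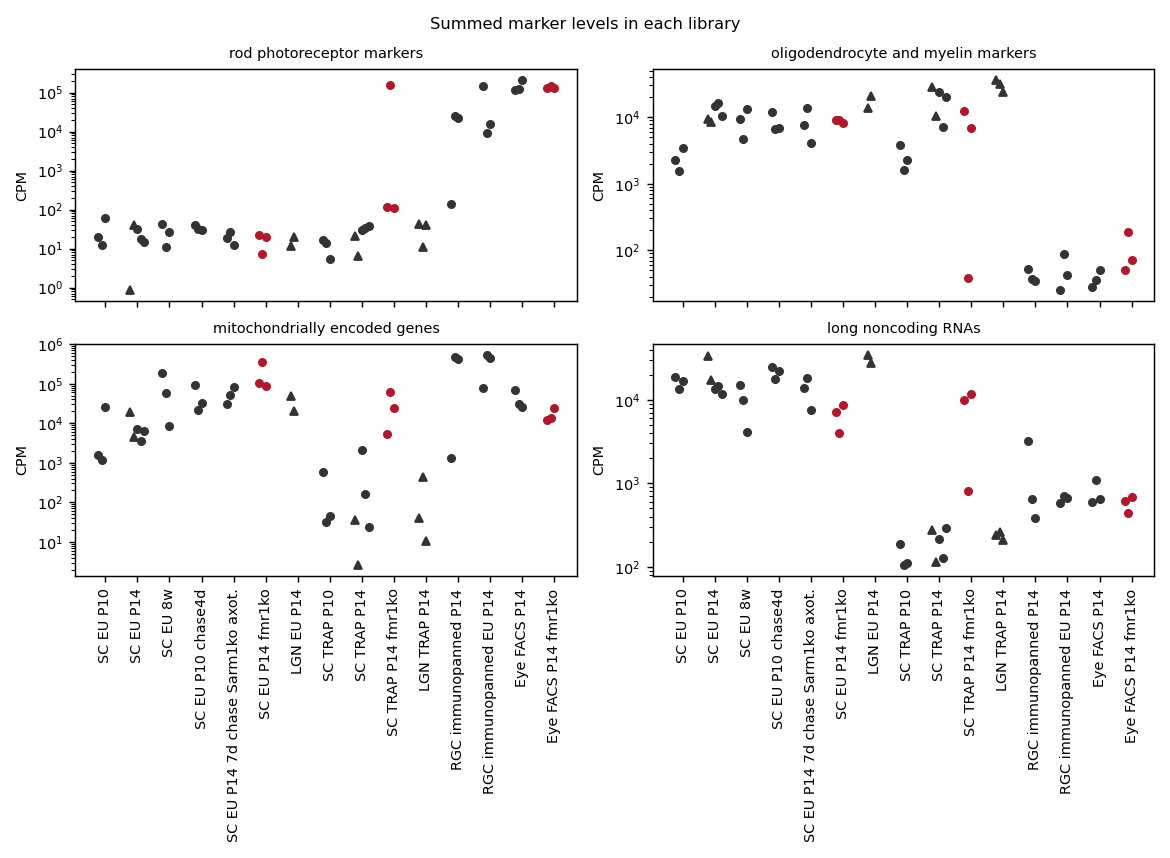
Summed CPM (log axis) of 4 gene lists in each library, with 1 point per library, triangles for the code series of the LGN libraries and red for libraries labelled fmr1ko. Rod markers are high in 1 TRAP library labelled fmr1ko and in the eye libraries other than immunopanned replicate 1 (143 CPM), and the long noncoding RNAs of EU libraries exceed those of wild-type TRAP libraries.

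**Figure D3:**
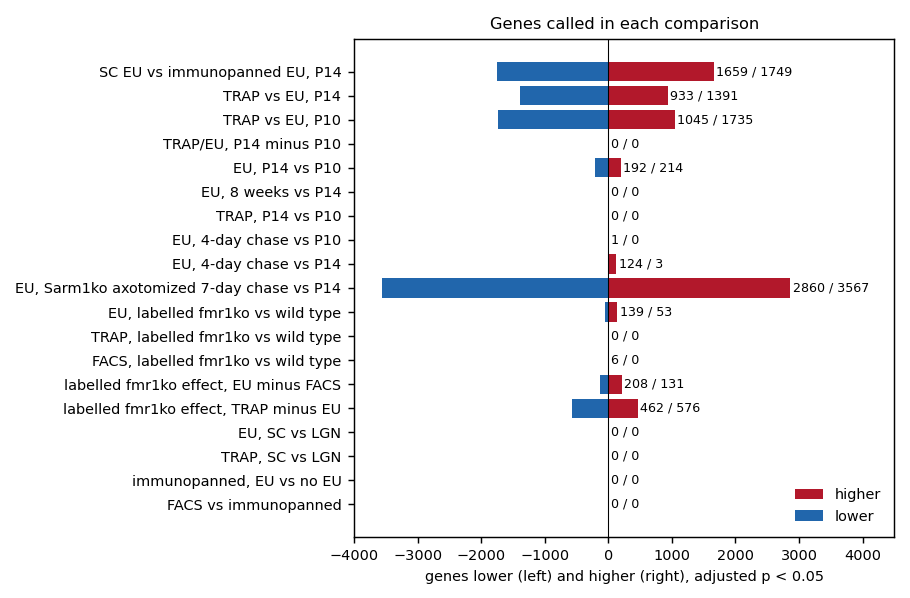
Number of genes called higher (right, red) and lower (left, blue) at adjusted p under 0.05 in each of the 16 comparisons and 3 interaction tests, with both counts printed beside each bar. The sarm1ko comparison has the most calls, 2860 higher and 3567 lower.

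Axonal RNA was set against somal RNA by comparing EU-labelled RNA of P14 SC with EU-labelled RNA of immunopanned RGC. Transcripts of axon growth and structure were higher in SC: Gap43 (growth-cone protein; chr 16, 42248442 to 42340651) had 655 ± 159 against 12.5 ± 6.35 normalised CPM (log2 fold change 5.71 ± 0.66, adjusted p = 0.0024). Tubb3 (neuronal tubulin) had 960 ± 209 against 86.3 ± 24.8, and Map1a (microtubule-binding protein) 564 ± 73.7 against 13.8 ± 13.1. Of 38 members of the axonal cytoskeleton and transport list, 16 were higher and 0 lower, and 22 did not pass. When adjusted over the list alone 19 were higher (median log2 fold change 1.66, camera adjusted p = 2.3e-05, adjusted p = 0.23 with an estimated correlation). Of 50 presynaptic genes, 21 were higher and 5 lower, and 24 higher and 6 lower when adjusted over the list alone (median log2 fold change 2.07, adjusted p = 0.0002, adjusted p = 0.13 with an estimated correlation). Vamp1, a vesicle SNARE, had 420 ± 65.7 against 21.1 ± 6.17. Of 67 reported FMRP-bound mRNAs, 28 were higher and 1 lower, and 31 and 1 when adjusted over the list alone (median log2 fold change 1.77, adjusted p = 1.4e-07, adjusted p = 0.13 with an estimated correlation). The postsynaptic kinase Camk2a, whose mRNA is localised in dendrites, had 149 ± 27.9 against 0.228 ± 0.338. The imprinted long noncoding RNA Meg3 (chr 12, 109541001 to 109571726) had 7970 ± 933 against 195 ± 81.1 (log2 fold change 5.36 ± 0.6, adjusted p = 0.0023). Whether the Meg3 RNA in SC came from RGC axons or from cells of SC was not tested. The 13 mitochondrially encoded genes were all lower, also when adjusted over the list alone (median log2 fold change −6.79, adjusted p = 3.7e-15, adjusted p = 0.2 with an estimated correlation). The level of mt-Cytb was 327 ± 115 against 36400 ± 23700. Reads shared with nuclear copies make these levels uncertain.

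Markers of cells other than RGC moved with both sides of this comparison. The rod list had 14 of 14 members lower in SC (14 when adjusted over the list alone; median log2 fold change −14.04, and −13.64 with genes at 0 set to their bound; adjusted p = 4.9e-25, adjusted p = 0.15 with an estimated correlation). Gnat1, the rod transducin, had 1.2 ± 0.532 against 11300 ± 13800 normalised CPM, and Pdc, which binds transducin, had no counts against 4860 ± 4850, at least 143000-fold lower. The oligodendrocyte and myelin list had 12 of 14 members higher in SC and 0 lower, and 13 when adjusted over the list alone (median log2 fold change 9.14, and 8.92 with genes at 0 set to their bound; adjusted p = 7.6e-16, adjusted p = 0.031 with an estimated correlation). Mbp (myelin basic protein; chr 18, 82475146 to 82585637) had 6720 ± 1590 against 15.4 ± 7.32 (log2 fold change 8.77 ± 0.71, adjusted p = 0.0013), and Mobp (chr 9, 120149707 to 120181484) had 1220 ± 155 against no counts, at least 23000-fold higher. Of 11 midbrain transcription factors, 7 were higher and 1 lower, and 8 and 1 when adjusted over the list alone (median log2 fold change 7.87, and 7.07 at the bounds; adjusted p = 0.00039, adjusted p = 0.13 with an estimated correlation). Gata3 had 63.6 ± 23.6 against 0.0247 ± 0.0428. Of 17 immediate early genes, which respond to activity and to handling of cells, 1 was higher and 8 lower, and 1 and 9 when adjusted over the list alone (median log2 fold change −3.27, adjusted p = 0.0022, adjusted p = 0.42 with an estimated correlation). Fos had 11.8 ± 6.12 against 663 ± 452. The RGC marker list itself was not called: of 17 members 5 were higher and 2 lower (median log2 fold change 0.23). Summed, however, RGC markers had 230.2, 587.2 and 800.9 CPM in the immunopanned EU libraries, against 2531, 3297 and 2448 CPM in P14 SC EU replicates 3 to 5. The sum holds Gap43 and Thy1, and its RGC origin was not tested.

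In all, 1659 of 15540 genes were higher and 1749 lower in axonal than in somal EU RNA (edgeR), and 46.8% of the genes had groups that did not overlap, where chance gives 10%. DESeq2 called 5698 genes, limma on TPM 5825 (4777 higher and 1048 lower), edgeR with the length trend removed 3751 (1382 higher and 2369 lower), and edgeR with the FACS libraries as soma 5972. With the immunopanned libraries without EU capture as soma it called 0, with 4709 genes at unadjusted p under 0.05. In that group replicate 1 stood apart, with a mean correlation of 0.181 with its own group, against 0.585 and 0.567 for replicates 2 and 3. That soma without replicate 1 was not tested, so the 0 cannot be credited to the choice of soma. With immunopanned EU libraries as soma, the count was 1040 without P14 EU replicate 3, 950 without replicate 4 and 1925 without replicate 5. Region, purification and cell type differ together between these groups, so that axonal and somal RNA cannot be separated from them here.

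Ribosome-bound RNA was compared with EU-labelled RNA of the same region at P14. Long noncoding RNAs, many of them reported as nuclear, were lower in TRAP libraries: Meg3 had 65.7 ± 22.3 against 11500 ± 1640 normalised CPM (log2 fold change −7.45 ± 0.46, adjusted p = 0.000089). Malat1 (chr 19, 5795690 to 5802672) had 15.5 ± 7.57 against 1470 ± 937 (log2 fold change −6.57 ± 0.65, adjusted p = 0.00081). Of 9 measured members of that list 7 were lower and 0 higher, and 8 lower when adjusted over the list alone (median log2 fold change −5.46, adjusted p = 4.5e-22, adjusted p = 0.042 with an estimated correlation). Among 67 reported FMRP-bound mRNAs, 1 was higher and 23 lower, and 1 and 30 when adjusted over the list alone (median log2 fold change −1.07, adjusted p = 3.5e-09, adjusted p = 0.12 with an estimated correlation). Map1a had 140 ± 37.3 against 812 ± 112, the guanine exchange factor Trio 32.8 ± 10.4 against 232 ± 31.1, and the histone methyltransferase Kmt2a 24.6 ± 10.2 against 224 ± 43.4. The kinase Camk2a had 25.3 ± 20.8 against 214 ± 37.6 in the postsynaptic list, of whose 25 members 5 were lower, and 1 higher and 8 lower when adjusted over the list alone (median log2 fold change −0.77, adjusted p = 0.014, adjusted p = 0.53 with an estimated correlation). Of 13 mitochondrially encoded genes 7 were lower, and 8 when adjusted over the list alone (median log2 fold change −4.36, adjusted p = 3.7e-10, adjusted p = 0.46 with an estimated correlation). The level of mt-Nd2 was 1.69 ± 1.78 against 106 ± 52.4.

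Some nuclear-encoded genes of energy metabolism and protein turnover were higher in P14 TRAP libraries. Of 80 oxidative phosphorylation genes 14 were higher and 0 lower, and 17 when adjusted over the list alone (median log2 fold change 0.58, adjusted p = 0.00011, adjusted p = 0.65 with an estimated correlation). The complex I subunit Ndufv2 had 351 ± 56 against 76.3 ± 31.3 normalised CPM. Of 38 proteasome genes 13 were higher, also when adjusted over the list alone (median log2 fold change 0.63, adjusted p = 0.00011, adjusted p = 0.46 with an estimated correlation). Of 78 mitochondrial ribosomal protein genes 10 were higher, and 9 when adjusted over the list alone (median log2 fold change 0.54, adjusted p = 0.00094, adjusted p = 0.65 with an estimated correlation). Microglial markers moved the same way, with 3 of 14 higher and 4 when adjusted over the list alone (median log2 fold change 1.03, adjusted p = 0.0078, adjusted p = 0.43 with an estimated correlation). The complement gene C1qb had 180 ± 50.3 against 54 ± 20.3, a call that ended without P14 TRAP replicate 4 (log2 fold change 1.55) or P14 EU replicate 3 (1.79). Eno1b, an intronless copy of the glycolytic gene Eno1 with which it shares reads, had 773 ± 386 against 2.97 ± 0.772 (log2 fold change 8.02 ± 0.55, adjusted p = 0.00014), and with all 5 P14 libraries per group the log2 fold change was 3.47 and not called. Of 16277 genes 933 were higher and 1391 lower, and 37.2% had groups that did not overlap, against 10% by chance. The count was 3842 with DESeq2, 3611 with no filter, 2725 with limma on TPM (1395 higher and 1330 lower) and 1379 with all 5 P14 libraries per group (319 higher and 1060 lower). It was 775, 953 and 727 without TRAP replicates 3, 4 and 5, 899 without EU replicate 3 and 4062 without EU replicate 5.

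At P10 the same comparison gave 1045 genes higher and 1735 lower in TRAP libraries of 15733 tested. Meg3 had 38.5 ± 26.2 against 12800 ± 2040 normalised CPM (log2 fold change −8.38 ± 0.65, adjusted p = 0.00012), Malat1 6.44 ± 3.93 against 898 ± 278 and Snhg11 10.4 ± 2.46 against 1290 ± 119. Of 9 long noncoding RNAs 7 were lower, and 8 when adjusted over the list alone (median log2 fold change −6.46, adjusted p = 2.1e-22, adjusted p = 0.015 with an estimated correlation). Of 67 reported FMRP-bound mRNAs 33 were lower, and 42 when adjusted over the list alone (median log2 fold change −1.41, adjusted p = 1.6e-11, adjusted p = 0.084 with an estimated correlation). Dync1h1, the heavy chain of the retrograde motor dynein, had 51.2 ± 9.2 against 354 ± 78.7. Of 25 voltage-gated channel genes 10 were lower, and 1 higher and 10 lower when adjusted over the list alone (median log2 fold change −1.37, adjusted p = 0.0013, adjusted p = 0.42 with an estimated correlation). The sodium channel Scn2a had 61.3 ± 23.6 against 307 ± 59.7. Of 78 mitochondrial ribosomal protein genes 22 were higher and 1 lower, also when adjusted over the list alone (median log2 fold change 0.78, adjusted p = 1.1e-06, adjusted p = 0.42 with an estimated correlation). Mrpl20 had 320 ± 119 against 65.7 ± 15.6. The respiratory complex III subunit Uqcrfs1 had 827 ± 264 against 155 ± 19.8. Microglial markers were again higher, with 4 of 14 called and 8 when adjusted over the list alone (median log2 fold change 1.03, adjusted p = 0.0028, adjusted p = 0.23 with an estimated correlation). Groups did not overlap in 38.9% of genes, against 10% by chance. The count was 1162, 1568 and 1626 without P10 EU replicates 1, 2 and 3, and 1850 without P10 TRAP replicate 3. It was 1448 with a replicate block and 3121 with limma on TPM (700 higher and 2421 lower).

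The TRAP to EU ratios of the 2 ages share no library, and across the 7039 genes compared they correlated with a Pearson coefficient of 0.657 and a Spearman coefficient of 0.586, with the same sign in 70% of genes. Genes are not independent replicates. The test of the difference between the ages called 0 of 18660 genes with edgeR, with 2056 at unadjusted p under 0.05, 166 called by DESeq2, 9 by limma on TPM, 335 with no filter and 1 with the length trend removed. It called 214 without P14 EU replicate 5, 29 without P10 TRAP replicate 1 and 1 without P10 TRAP replicate 2. Of the lists, 1 passed: of 14 midbrain transcription factors 0 were called, and 3 were lower at P14 when adjusted over the list alone (median log2 difference −1.04, adjusted p = 0.033, adjusted p = 0.28 with an estimated correlation).

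**Figure D4:**
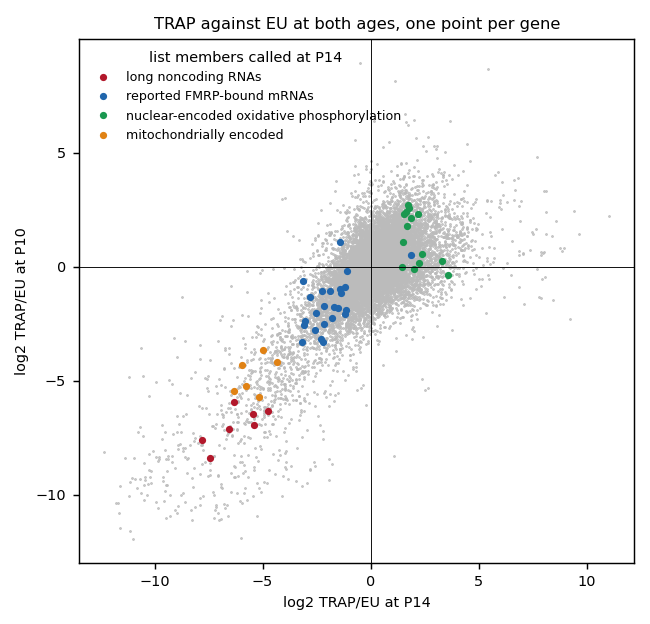
Log2 TRAP to EU ratio at P14 (horizontal axis) and P10 (vertical axis), with 1 grey point per gene and coloured points for members of 4 gene lists called at P14. The long noncoding RNAs and mitochondrially encoded genes lie at negative ratios on both axes.

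Between P10 and P14, myelin genes rose in EU RNA of SC. Mobp had 1710 ± 253 against 181 ± 42.5 normalised CPM (log2 fold change 3.24 ± 0.31, adjusted p = 0.00089). Mbp had 9450 ± 2370 against 1090 ± 238 (log2 fold change 3.12 ± 0.32, adjusted p = 0.0014) and Cnp 2050 ± 217 against 465 ± 88.7. Of 15 oligodendrocyte and myelin genes 7 were higher, and 10 when adjusted over the list alone (median log2 fold change 2.13, adjusted p = 3.8e-16, adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes fell: of 83 members 27 were lower, and 55 when adjusted over the list alone (median log2 fold change −1.18, adjusted p = 5e-30, adjusted p = 0.32 with an estimated correlation). Rps24 had 30.2 ± 20.4 against 565 ± 161, though reads shared with pseudogenes make single members uncertain. Of 80 oxidative phosphorylation genes 1 was higher and 7 lower, and 5 and 29 when adjusted over the list alone (median log2 fold change −0.7, adjusted p = 3.3e-09, adjusted p = 0.52 with an estimated correlation). Ndufa4 had 50.8 ± 18.7 against 329 ± 19.8. Of 16 glycolytic genes 3 were higher, and 8 when adjusted over the list alone (median log2 fold change 0.78, adjusted p = 2.3e-05, adjusted p = 0.52 with an estimated correlation). The neuronal enolase Eno2 had 730 ± 254 against 135 ± 8.24. Another of the 3, Aldoc, is also an astrocyte marker, and of 15 astrocyte genes 3 were higher, and 6 when adjusted over the list alone (median log2 fold change 0.88, adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation). Fabp7, a fatty acid-binding protein of radial glia (chr 10, 57784881 to 57788450), had 7.39 ± 6.46 against 515 ± 208 (log2 fold change −6.13 ± 0.67, adjusted p = 0.0018). Of 16262 genes 192 were higher and 214 lower, and 25.7% had groups that did not overlap, against 10% by chance. The count was 58, 151 and 2160 without P14 replicates 3, 4 and 5, and 42, 130 and 108 without P10 replicates 1, 2 and 3. It was 1382 with DESeq2, 1154 with no filter, 472 with limma on TPM (149 higher and 323 lower) and 610 with a replicate block. With all 5 P14 EU libraries it was 18, all lower, and Mobp, Mbp, Cnp, Eno2 and Fabp7 were no longer called (log2 fold changes 2.84, 2.66, 1.61, 1.84 and −4.35).

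In TRAP libraries, edgeR called 0 of 15752 genes between P10 and P14, with 2290 at unadjusted p under 0.05, 760 called by DESeq2, 0 by limma on TPM and 833 with no filter. Mobp had 1340 ± 957 normalised CPM at P14 against 121 ± 58.2 at P10 (adjusted p = 0.14), Rpl10 74.6 ± 26 against 447 ± 180 (adjusted p = 0.14) and the glutamate transporter Slc1a2 920 ± 323 against 210 ± 9.97. The lists that moved most were the myelin list, with 12 of 15 members higher when adjusted over the list alone (median log2 fold change 2.45, adjusted p = 2.2e-12, adjusted p = 0.54 with an estimated correlation), and the ribosomal protein list. Of its 83 members 45 were lower when adjusted over the list alone (median log2 fold change −1.47, adjusted p = 5.3e-30, adjusted p = 0.54 with an estimated correlation). Across 6583 genes the change with age correlated between EU and TRAP libraries with a Pearson coefficient of 0.377 (0.235 over all tested genes) and a Spearman coefficient of 0.332, and 58.8% of genes had the same sign. Genes are not independent replicates. Groups did not overlap in 22% of genes, against 10% by chance. The count was 253 without P10 TRAP replicate 1, 1 without P10 TRAP replicate 3 and 1 without P14 TRAP replicate 3.

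Between P14 and 8 weeks, edgeR called 0 of 16942 genes in EU RNA, with 1496 at unadjusted p under 0.05, 803 called by DESeq2, 1 by limma on TPM and 418 with no filter. The mitochondrially encoded list was higher at 8 weeks, with 0 of 13 members called among all genes and 13 when adjusted over the list alone (median log2 fold change 4.01, adjusted p = 3.9e-13, adjusted p = 0.74 with an estimated correlation). Libraries at 8 weeks differed: mitochondrially encoded genes, also those outside the list, took 21.1%, 33.8% and 0.905% of the counts in replicates 1 to 3. The 13 of the list summed to 188900, 58750 and 8495 CPM. Replicate 3 correlated with the P14 libraries at 0.851 and with 8-week replicates 1 and 2 at 0.616. Without P14 replicate 5 the count was 1. Without 8-week replicate 3 (n = 2 against 3) it was 3360, with 1704 higher and 1656 lower. In that fit Gpr17, of oligodendrocyte precursors, had 12.1 ± 1.96 against 329 ± 93.2 normalised CPM (adjusted p = 0.012). Etnppl, an astrocytic phospholyase, had 110 ± 4.92 against 0.982 ± 0.655, and Anln, an actin-binding protein, 51.7 ± 15.2 against 0.175 ± 0.199. In the same fit 13 of 13 mitochondrially encoded genes were higher (median log2 fold change 4.54, adjusted p = 5.6e-18, or 0.2 with an estimated correlation). Of 38 axonal cytoskeleton and transport genes 16 were lower and 3 higher (median log2 fold change −1.04). With all libraries groups did not overlap in 12.3% of genes (chance 10%).

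In the chase libraries, EU given at P10 was followed by 4 days without label. Against P10, myelin genes were again higher and ribosomal protein genes lower as lists. Of 15 myelin genes 11 were higher when adjusted over the list alone (median log2 fold change 1.66, adjusted p = 4.3e-12, adjusted p = 0.6 with an estimated correlation). Of 83 ribosomal protein genes 70 were lower when adjusted over the list alone (median log2 fold change −1.14, adjusted p = 1.9e-39, adjusted p = 0.6 with an estimated correlation). Mobp had 715 ± 275 against 211 ± 45.1 normalised CPM (adjusted p = 0.14). Rpl13 had 299 ± 79.2 against 1070 ± 312, and Gap43 had 650 ± 366 against 1640 ± 567 (adjusted p = 0.18). Of 80 oxidative phosphorylation genes 1 was higher and 39 lower when adjusted over the list alone (median log2 fold change −0.74, adjusted p = 1.7e-15, adjusted p = 0.6 with an estimated correlation). Among all 16746 genes edgeR called 1, the predicted gene Gm10925 (higher, adjusted p = 0.0078), which was chosen after its values were seen, with 3041 at unadjusted p under 0.05 and 25.6% without overlap against 10% by chance. DESeq2 called 983 genes, limma on TPM 2 and edgeR with no filter 1055. The count was 2 and 3 without chase replicates 1 and 2, 0 without P10 replicate 1, 0 without P10 replicate 2 and 37 without P10 replicate 3.

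Against P14, the chase libraries had the same age but label from 4 days before. Fabp7 had 174 ± 96.2 against 7.77 ± 6.7 normalised CPM (log2 fold change 4.49, adjusted p = 0.032). The same P14 libraries were also low in Fabp7 against P10, so a chase effect cannot be told apart from low values of these libraries. Hnrnpa0, a splicing-related RNA-binding protein, had 60.1 ± 23.2 against 2.56 ± 1.79, and Chm, a Rab escort protein, 34 ± 11.6 against 0.814 ± 0.882. Gsn, the actin-severing gelsolin, had 85.9 ± 10.2 against 304 ± 59.1 (log2 fold change −1.82, adjusted p = 0.032). Of 13 mitochondrially encoded genes 4 were higher, and 13 when adjusted over the list alone (median log2 fold change 2.44, adjusted p = 1.4e-11, adjusted p = 0.64 with an estimated correlation). The level of mt-Co2 was 8110 ± 6150 against 748 ± 238. Of 16 glycolytic genes 8 were lower when adjusted over the list alone and 0 among all genes (median log2 fold change −0.92, adjusted p = 4.7e-05, adjusted p = 0.64 with an estimated correlation). Across 7190 genes the TRAP to EU ratio at P14 and the change from P10 to the chase correlated with a Pearson coefficient of 0.165 (0.028 over all tested genes, 0.082 to 0.288 without 1 library) and a Spearman coefficient of 0.183, and genes are not independent replicates. Of 17513 genes 124 were higher and 3 lower, with 31.7% without overlap against 10% by chance. The count was 1, 1 and 18 without chase replicates 1, 2 and 3, and 4, 4 and 4227 without P14 replicates 3, 4 and 5. It was 1982 with DESeq2, 1182 with limma on TPM, 1563 with no filter, 436 with a replicate block, 273 with the length trend removed, 82 without CT010467.1 and the mitochondrially encoded genes and 0 with all 5 P14 EU libraries. Each of the 5 called genes named here lost its call without chase replicates 1 or 2 and without P14 replicates 3 or 4, and all but Hnrnpa0 also without chase replicate 3. The log2 fold change of Fabp7 then ran from 4.04 to 4.89.

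The sarm1ko libraries differ from the wild-type P14 EU libraries in genotype, axotomy, a 7-day chase and the age that comes with it, and these cannot be told apart. Among the axonal and presynaptic transcripts lower in them, Tubb3 had 226 ± 21.5 against 975 ± 248 normalised CPM (log2 fold change −2.11 ± 0.3, adjusted p = 0.0018) and Gap43 198 ± 31.3 against 665 ± 184 (log2 fold change −1.74 ± 0.3, adjusted p = 0.0031). Tubb2a had 240 ± 72.6 against 1630 ± 471, the vesicle GTPase Rab3a 112 ± 18.2 against 860 ± 329 and the neuronal surface protein Thy1 83.4 ± 19.7 against 639 ± 236. Of 38 axonal cytoskeleton and transport genes 6 were higher and 20 lower, and 6 and 21 when adjusted over the list alone (median log2 fold change −1.03, adjusted p = 0.00065, adjusted p = 0.52 with an estimated correlation). Of 50 presynaptic genes 6 were higher and 23 lower, and 9 and 25 when adjusted over the list alone (median log2 fold change −0.68, adjusted p = 0.0036, adjusted p = 0.52 with an estimated correlation). Over all genes with an average log2 CPM of at least 4 the median log2 fold change was −0.709, so the presynaptic median was no lower than that of abundant genes in general. Of 80 nuclear-encoded oxidative phosphorylation genes 1 was higher and 58 lower, and 1 and 61 when adjusted over the list alone (median log2 fold change −1.8, adjusted p = 2.3e-17, adjusted p = 0.52 with an estimated correlation). Cox6a1 had 34 ± 7.68 against 423 ± 165. Of 83 ribosomal protein genes 2 were higher and 47 lower, and 3 and 54 when adjusted over the list alone (median log2 fold change −1.47, adjusted p = 2.9e-14, adjusted p = 0.52 with an estimated correlation).

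Mitochondrially encoded transcripts went the other way in the sarm1ko libraries, with 13 of 13 higher, also when adjusted over the list alone (median log2 fold change 4.59, adjusted p = 1.6e-13, adjusted p = 0.52 with an estimated correlation). For mt-Atp8 the levels were 429 ± 261 against 7.69 ± 2.74 normalised CPM (log2 fold change 5.8 ± 0.53, adjusted p = 0.0015). Of 16 glycolytic genes 13 were lower, and 14 when adjusted over the list alone (median log2 fold change −1.71, adjusted p = 7.8e-08, adjusted p = 0.52 with an estimated correlation). Eno1 had 167 ± 33.7 against 1020 ± 292. Oligodendrocyte precursor genes were lower, 5 of 10 and 6 when adjusted over the list alone (median log2 fold change −1.49, adjusted p = 0.0045, adjusted p = 0.52 with an estimated correlation). Gpr17 (chr 18, 31942997 to 31949636) had 13.1 ± 3.65 against 264 ± 79.7. Gad1, which makes GABA, had 243 ± 46.8 against 45.2 ± 33.1. Fmr1 had 18.1 ± 1.78 against 0.897 ± 0.498 (log2 fold change 4.32, adjusted p = 0.0018). Of 17171 genes 2860 were higher and 3567 lower, and 57.8% had groups that did not overlap, against 10% by chance. The count was 2743 and 2901 without sarm1ko replicates 1 and 3, 3714 without P14 replicate 3, and 10336 without P14 replicate 5. It was 964 with all 5 P14 EU libraries, where Cox6a1 (log2 fold change −3.08) was not called, and 5999 with limma on TPM (1688 higher and 4311 lower).

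In EU libraries labelled fmr1ko, in which Fmr1 was not called lower, mitochondrially encoded genes were higher than in wild type: 12 of 13, and 13 when adjusted over the list alone (median log2 fold change 5.33, adjusted p = 3.3e-22, adjusted p = 0.76 with an estimated correlation). For mt-Nd4 the level was 18600 ± 13700 against 446 ± 104 normalised CPM (log2 fold change 5.38 ± 0.61, adjusted p = 0.025). Mitochondrially encoded genes, also those outside the list, took 11.3%, 40% and 9.58% of the counts of the 3 libraries labelled fmr1ko. Of 37 proteasome genes 2 were higher, and 9 when adjusted over the list alone (median log2 fold change 0.5, adjusted p = 0.024, adjusted p = 0.76 with an estimated correlation). Psma5 had 114 ± 6.36 against 37.7 ± 9.99 (adjusted p = 0.045). Nr2f2, an orphan nuclear receptor, had 5.29 ± 1.24 against 46.6 ± 21.7 (log2 fold change −3.14 ± 0.48, adjusted p = 0.036), and Gsk3a, a kinase of glycogen and Wnt signalling, 5.79 ± 1.8 against 30.2 ± 8.21 (adjusted p = 0.046). Eno1b, which shares reads with Eno1, had 568 ± 428 against 2.59 ± 0.707 (log2 fold change 7.78 ± 0.65, adjusted p = 0.0089). The list of reported FMRP-bound mRNAs was not called (adjusted p = 0.1): of 67 members 1 was higher and 1 lower, and 4 and 14 when adjusted over the list alone (median log2 fold change −0.23). Of 16546 genes 139 were higher and 53 lower, with 32.1% without overlap against 10% by chance. The count was 13, 25 and 72 without fmr1ko replicates 1, 2 and 3, 0 without P14 replicate 3, 0 without P14 replicate 4 and 3499 without P14 replicate 5. The named genes lost their calls without either of P14 replicates 3 and 4, and Psma5, Nr2f2 and Gsk3a also without any 1 of the libraries labelled fmr1ko. The count was 2369 with DESeq2, 624 with limma on TPM (333 higher and 291 lower), 1263 with no filter, 4 with a replicate block, 6 with all 5 P14 EU libraries and 421 with the length trend removed.

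In TRAP libraries labelled fmr1ko, in which Fmr1 was not called lower, edgeR called 0 of 16115 genes, with 2830 at unadjusted p under 0.05, 2431 called by DESeq2 and 94 by limma on TPM, and 847 by edgeR with all 5 P14 TRAP libraries. Rod markers were higher as a list, with 11 of 11 when adjusted over the list alone (median log2 fold change 12.97, adjusted p = 7.5e-05, adjusted p = 0.65 with an estimated correlation). Replicate 2 carried most of this: rod markers summed to 119.6, 153000 and 113.1 CPM in replicates 1 to 3, and without it the median log2 fold change was 3.05, with 1 of 11 called (adjusted p = 0.000087, adjusted p = 0.26 with an estimated correlation). Replicate 2 correlated with wild-type FACS eye libraries at 0.897 and with wild-type P14 TRAP libraries at 0.485, and its myelin markers summed to 38.1 CPM against 12500 and 6990 CPM in replicates 1 and 3. Of 9 long noncoding RNAs 7 were higher when adjusted over the list alone (median log2 fold change 4.16, adjusted p = 2.9e-06, adjusted p = 0.44 with an estimated correlation). Of 79 oxidative phosphorylation genes 46 were lower when adjusted over the list alone (median log2 fold change −1.85, adjusted p = 9.8e-13, adjusted p = 0.44 with an estimated correlation). Without replicate 2 the count was 348, of which 225 were higher. In that fit (n = 2 against 3) Meg3 had 7290 ± 756 against 76.4 ± 25.2 normalised CPM (adjusted p = 0.01) and C1qb 8.06 ± 0.372 against 210 ± 60.5 (adjusted p = 0.017). There 5 of the long noncoding RNAs were higher (median log2 fold change 4.72, adjusted p = 1.8e-11, adjusted p = 0.26 with an estimated correlation), as were 7 reported FMRP-bound mRNAs (median log2 fold change 0.98, adjusted p = 2.7e-10, adjusted p = 0.12 with an estimated correlation). Replicates 1 and 3 correlated with the EU libraries labelled fmr1ko at 0.79 and 0.792 and with wild-type P14 TRAP libraries at 0.765 and 0.748. Groups did not overlap in 29.4% of genes, against 10% by chance.

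In FACS-sorted eye cells labelled fmr1ko, in which Fmr1 was not called lower, 6 of 15165 genes were higher than in wild type and 0 lower. They were Rax, a retinal progenitor homeobox gene (218 ± 34.6 against 25.2 ± 2.6 normalised CPM, log2 fold change 3.11, adjusted p = 0.028) and Pcsk1n, a proprotein convertase inhibitor (148 ± 45.3 against 7.49 ± 2.03, log2 fold change 4.31 ± 0.39, adjusted p = 0.041). The other 4 were Sdhaf1 (162 ± 63.5 against 14 ± 1.71), Zfp428 (139 ± 25.6 against 17.9 ± 4.82, adjusted p = 0.047), Arglu1 (261 ± 8.42 against 37.8 ± 11.9) and B4galt1 (359 ± 59.4 against 76.7 ± 7.9). Of 84 ribosomal protein genes 59 were higher when adjusted over the list alone (median log2 fold change 1.38, adjusted p = 7.4e-53, adjusted p = 0.4 with an estimated correlation). Of 79 oxidative phosphorylation genes 39 were higher and 3 lower when adjusted over the list alone (median log2 fold change 0.96, adjusted p = 2.2e-25, adjusted p = 0.4 with an estimated correlation). Of 13 mitochondrially encoded genes 8 were lower when adjusted over the list alone (median log2 fold change −1.39, adjusted p = 8.3e-06, adjusted p = 0.64 with an estimated correlation). Hemoglobin and other erythroid genes were higher, 4 of 5 when adjusted over the list alone (median log2 fold change 3.38, adjusted p = 4.5e-10, adjusted p = 0.083 with an estimated correlation). At unadjusted p under 0.05 there were 1904 genes, and 22.3% had groups that did not overlap, against 10% by chance. The count was 0 without any 1 of the 3 libraries labelled fmr1ko, 0 without wild-type replicate 1, 0 without wild-type replicate 2 and 1 without wild-type replicate 3. It was 1097 with DESeq2, 28 with limma on TPM, 128 with no filter, 0 with a replicate block and 2 with the length trend removed.

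The effect of the fmr1ko label differed between EU libraries of SC and FACS-sorted eye cells for 339 of 18886 genes, 208 with a higher and 131 with a lower effect in EU libraries. Fmr1 was not called lower under the label in either kind of library. Of 13 mitochondrially encoded genes 12 had a higher effect in EU libraries, and 13 when adjusted over the list alone (median log2 difference 6.67, adjusted p = 2.5e-24, adjusted p = 0.37 with an estimated correlation). The gene mt-Nd4 had a log2 difference of 7.03 ± 0.82 (adjusted p = 0.0095). Of 84 ribosomal protein genes 13 had a lower effect, and 5 a higher and 39 a lower effect when adjusted over the list alone (median log2 difference −1.24, adjusted p = 2.6e-14, adjusted p = 0.45 with an estimated correlation). Of 6 erythroid genes 3 had a lower effect, and 4 when adjusted over the list alone (median log2 difference −4.35, adjusted p = 8.5e-06, adjusted p = 0.41 with an estimated correlation). Across 5367 genes the effects in EU and FACS libraries correlated with a Pearson coefficient of −0.148 (−0.081 over all tested genes) and a Spearman coefficient of −0.135, and genes are not independent replicates. The count was 40 and 71 without fmr1ko EU replicates 1 and 2, 49, 42 and 1462 without P14 EU replicates 3, 4 and 5, and 107 and 153 without wild-type FACS replicates 2 and 3. It was 2277 with DESeq2, 169 with limma on TPM and 522 with the length trend removed (161 higher and 361 lower).

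The effect of the fmr1ko label differed between TRAP and EU libraries for 1038 of 18561 genes, 462 with a higher and 576 with a lower effect in TRAP libraries. Of 10 long noncoding RNAs 5 had a higher effect, and 8 when adjusted over the list alone (median log2 difference 4.82, adjusted p = 1.7e-07, adjusted p = 0.28 with an estimated correlation). Malat1 had a log2 difference of 6.54 ± 0.89 (adjusted p = 0.011). Of 80 oxidative phosphorylation genes 19 had a lower effect, and 53 when adjusted over the list alone (median log2 difference −2.04, adjusted p = 4.2e-12, adjusted p = 0.38 with an estimated correlation). Of 67 reported FMRP-bound mRNAs 5 had a higher effect, and 6 when adjusted over the list alone (median log2 difference 0.83, adjusted p = 0.00065, adjusted p = 0.71 with an estimated correlation). The rod-rich replicate 2 is among the TRAP libraries, and of 9 rod markers 3 had a higher effect, and 8 when adjusted over the list alone (median log2 difference 11.33, adjusted p = 0.00065, adjusted p = 0.56 with an estimated correlation). Across 7018 genes the effects in EU and TRAP libraries correlated with a Pearson coefficient of −0.019 (−0.092 to 0.075 without 1 library) and a Spearman coefficient of −0.082, and genes are not independent replicates. The count was 2755 without fmr1ko TRAP replicate 2, 26, 22 and 20 without P14 TRAP replicates 3, 4 and 5, 4, 8 and 4 without fmr1ko EU replicates 1, 2 and 3, and 7 and 8 without P14 EU replicates 3 and 4. Malat1 lost its call without fmr1ko EU replicates 1 (log2 difference 6.28) or 3 (6.38). The count was 3125 with DESeq2, 409 with limma on TPM (303 higher and 106 lower), 581 with no filter, 4 with a replicate block and 1043 with the length trend removed (675 higher and 368 lower).

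SC and LGN, the 2 targets of RGC axons, were compared within the code series of the LGN libraries, with 2 SC libraries against 2 LGN libraries for EU and 2 against 3 for TRAP. Transcription factors of the midbrain were higher in SC as a list and thalamic markers lower, in both kinds of library. Of 9 midbrain factors in EU RNA 3 were higher when adjusted over the list alone (median log2 fold change 2.7, adjusted p = 4.3e-06, adjusted p = 0.48 with an estimated correlation). Sox14 had 54.7 ± 18.4 against 2.37 ± 3.08 normalised CPM and Tfap2d had 53 ± 44.2 against no counts, at least 222-fold higher (adjusted p = 0.74, n = 2 each). Of 11 midbrain factors in TRAP RNA 4 were higher when adjusted over the list alone (median log2 fold change 2.89, adjusted p = 4.3e-09, adjusted p = 0.26 with an estimated correlation). Gata3 had 127 ± 99.4 against 8.94 ± 1.59 (adjusted p = 0.44). Thalamic markers had a median log2 fold change of −1.7 over 15 members in EU RNA (adjusted p = 3.6e-06, adjusted p = 0.48 with an estimated correlation). It was −1.53 over 15 members in TRAP RNA, where 4 were lower when adjusted over the list alone (adjusted p = 1.3e-09, adjusted p = 0.26 with an estimated correlation). The neuropeptide gene Cck had 31.4 ± 36.8 against 317 ± 68.9 in EU RNA and 109 ± 80.8 against 1960 ± 520 in TRAP RNA (adjusted p = 0.5). Across 6508 genes the difference between SC and LGN correlated between EU and TRAP libraries with a Pearson coefficient of 0.326 (0.142 to 0.403 without 1 library) and a Spearman coefficient of 0.207, and genes are not independent replicates. In EU RNA edgeR called 0 of 15448 genes, with 470 at unadjusted p under 0.05, 72 called by DESeq2, 0 by limma on TPM, 15 with no filter, 80 with a replicate block, 2 with the length trend removed and 1 with RLE size factors. It called 3 and 10 without SC replicates 1 and 2 and 3 and 9 without LGN replicates 1 and 2. In TRAP RNA it called 0 of 15551 genes, with 408 at unadjusted p under 0.05, 70 called by DESeq2, 0 by limma on TPM, 44 with no filter, 20 with a replicate block and 4 without SC replicate 1.

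Immunopanned RGC with EU capture were compared with those without it. Of 13 lens and pigment epithelium genes 4 were lower with EU capture when adjusted over the list alone (median log2 fold change −7.47). The lens crystallin Cryba1 had 193 ± 161 against 134000 ± 120000 normalised CPM, a level made up by immunopanned replicates 2 and 3. Of 12 immediate early genes 3 were higher when adjusted over the list alone (median log2 fold change 3.46, adjusted p = 2.5e-06, adjusted p = 0.83 with an estimated correlation). Junb had 49.2 ± 38.2 against 0.79 ± 0.469 (adjusted p = 0.41). Nefl, a neurofilament of RGC, had 97.7 ± 76.4 against 278 ± 241. By edgeR 0 of 13360 genes were called, with 1183 at unadjusted p under 0.05, 238 called by DESeq2, 1678 by limma on TPM (1673 higher and 5 lower), 1176 with no filter and 25 without immunopanned replicate 1. Groups had no overlap in 18.8% of genes (chance 10%).

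FACS-sorted eye cells were compared with immunopanned RGC, and markers of several cell types differed. Rod markers summed to 151000 ± 53900 against 15700 ± 13500 CPM, while the rod list was not called (median log2 fold change 0.56). Of 12 lens and pigment epithelium genes 10 were lower in FACS cells when adjusted over the list alone (median log2 fold change −11.31, adjusted p = 3.2e-08, adjusted p = 0.45 with an estimated correlation), and crystallins took 30.2% and 33% of the counts of immunopanned replicates 2 and 3. RGC markers were lower in FACS cells, with 4 of 13 called when adjusted over the list alone (median log2 fold change −3.59, adjusted p = 3.8e-06, adjusted p = 0.45 with an estimated correlation). Slc17a6, the vesicular glutamate transporter of RGC, had 0.0428 ± 0.0461 against 15.5 ± 6.19 normalised CPM (adjusted p = 0.24). Amacrine and horizontal cell markers were also lower, with 6 of 11 called when adjusted over the list alone (median log2 fold change −4.18, adjusted p = 1.4e-06, adjusted p = 0.37 with an estimated correlation). Gad1 had 1.86 ± 1.34 against 76.4 ± 47.3. By edgeR 0 of 15489 genes were called, with 2676 at unadjusted p under 0.05, 1832 called by DESeq2, 8959 by limma on TPM (8917 higher and 42 lower), 1060 with no filter and 5013 without immunopanned replicate 1. Groups had no overlap in 37.7% of genes (chance 10%).

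**Figure D5:**
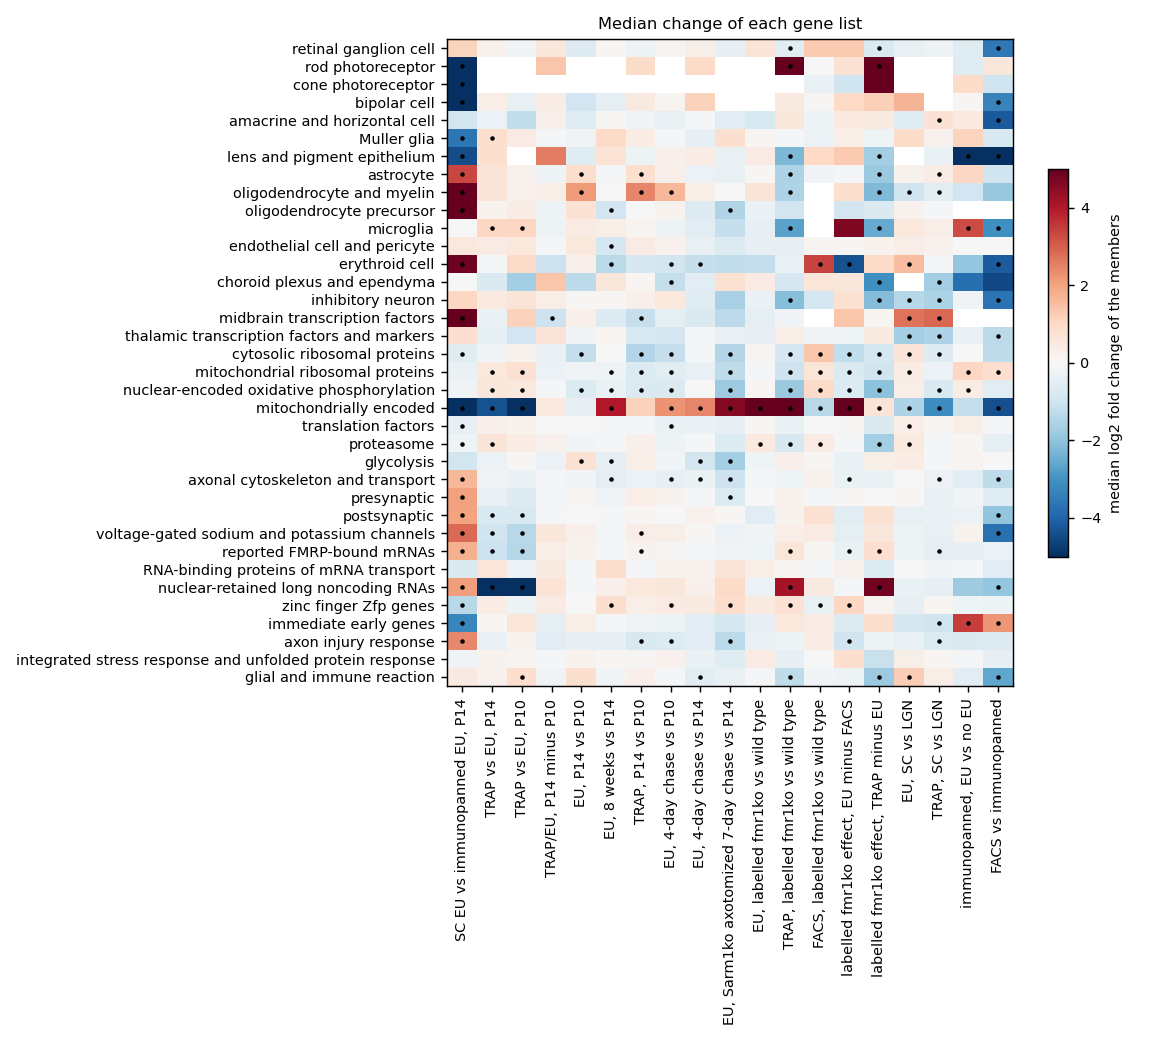
Median log2 fold change (colour, limited to ±5) of each gene list (vertical axis) in each comparison (horizontal axis), with a dot where camera with the preset correlation gave adjusted p under 0.05 and white where fewer than 5 members were tested. The mitochondrially encoded list has dots in most comparisons, in both directions.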

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

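Dixon's ratio, at its 95% critical value, was applied only to the P14 SC groups of 5 libraries. It picked out 5 of 24 groups of values, where chance picks about 1 in 20. Fmr1 reached 8.09 CPM in P14 SC EU replicate 2, apart from the other 4 libraries of its group. Malat1 reached 6310 CPM in P14 SC EU replicate 1. Mitochondrially encoded genes took 0.233% of the counts of P14 SC TRAP replicate 3. In P14 SC TRAP replicate 4, CT010467.1 took 2.04% and hemoglobin genes 2.46% of the counts.

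The effect of the fmr1ko label differed between kinds of library by an interaction test, for 339 genes between EU and FACS libraries and for 1038 genes between TRAP and EU libraries. None of the TRAP libraries labelled fmr1ko was nearest to a TRAP group by mean correlation. In 50 splits that exchanged the labels within each kind of library, the highest other counts were 194 and 75. Only the real split reached the real count. The splits assume no label effect in either kind, so they cannot exclude chance here. For the interaction of age with the TRAP to EU ratio the real count was 0 and the highest other count 0. Any split reaches a count of 0, so its 50 splits say nothing about chance.

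For the comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. Real count and highest count of the other splits were 3408 and 0 for axonal against somal EU RNA, 2324 and 0 for TRAP against EU at P14, 2780 and 0 for TRAP against EU at P10, and 406 and 0 for EU at P14 against P10. They were 1 and 0 for the chase against P10, 127 and 0 for the chase against P14, 6427 and 0 for sarm1ko, and for the fmr1ko label 192 and 0 in EU and 6 and 0 in FACS libraries. In each of these, 1 of the 10 splits, the real one, reached the real count. A real count of 0 is reached by any split, so the splits say nothing for TRAP at P14 against P10 (highest other 2), the fmr1ko label in TRAP libraries (0), and both comparisons among eye-cell libraries (0 and 0). For 8 weeks against P14 the real count was 0 and the highest other 3756, from the split that exchanged 8-week replicate 3 with P14 EU replicate 5, which points to a structure of the samples other than the 8-week label.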

How the results depend on the processing

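Removal of a trend on transcript length and the fit without CT010467.1 and the mitochondrially encoded genes were tried after seeing the data. Counts called were within 1.5 times those of the report for 18 of 19 tests with RLE size factors, 18 of 19 without CT010467.1 and the mitochondrially encoded genes, 13 of 19 with the length trend removed, 7 of 19 with limma on TPM, 7 of 15 with a replicate block, 5 of 19 with no filter and 2 of 19 with DESeq2. The count stayed within that range in 52 of 129 fits without 1 library, and of the others 26 gave more and 51 fewer. Named genes kept direction and side of the threshold in 97.7% of cases with RLE size factors, 95.7% with DESeq2, 93.7% with no filter, 92.7% with the length trend removed, 81.7% with limma on TPM, 72.1% with a replicate block, 69.4% without 1 library, 58.6% with all wild-type P14 SC libraries and 0 of 79 with RGC_immunopanned_P14 as the soma. Of 188 lists called with the preset correlation, 3 held with an estimated correlation: myelin in axonal against somal EU RNA and long noncoding RNAs in TRAP against EU at both ages. With RLE size factors 1 of the 188 was lost, the thalamic list in FACS against immunopanned cells (adjusted p = 0.059 against 0.025), and 0 medians changed sign. The median of all genes shifted by −0.54 there, by −0.21 for immunopanned cells with and without EU, and by −0.11 and 0.18 for the 2 interactions of the fmr1ko label. In no comparison with 3 or more pairs did all pairs of equal code digits correlate above 0.1. The 2 pairs of SC and LGN did (0.372 for EU, 0.444 to 0.483 for TRAP). The replicate block was not run for comparisons between code series without common digits, and where leaving out a library left 1 in a group, that library is assumed to vary like the others. The cause of these differences was not tested.

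With DESeq2 the counts were 5698 for axonal against somal EU RNA, 3842 for TRAP against EU at P14, 166 for the change of that ratio with age, 1382 for EU age, 803 for 8 weeks, and 760 for TRAP age. They were 983 for the chase against P10, 1982 for the chase against P14, 2369, 2431 and 1097 for the fmr1ko label in EU, TRAP and FACS libraries. They were 2277 and 3125 for its interactions EU minus FACS and TRAP minus EU, 72 and 70 for SC against LGN in EU and TRAP, 238 for immunopanned cells with EU against without and 1832 for FACS against immunopanned cells. With limma on TPM, in the same order where the count moved, they were 5825, 9 for the ratio, 1 for 8 weeks, 2 and 1182 for the chase, 624, 94 and 28 for the fmr1ko label, 169 and 409 for its interactions, 1678 and 8959 for the eye cells. The higher and lower calls were 700 and 2421 for TRAP against EU at P10 and 1395 and 1330 at P14. Genes picked by the naming rule that reversed were Gramd4 (−0.51) and Slitrk5 (−0.11) with limma on TPM, Junb (0.62) with RGC_immunopanned_P14 as the soma, 1 further gene (0.82) with Eye_FACS_P14 as the soma, and Fmr1 in TRAP libraries with the length trend removed (0.27). The axonal comparison called 0 genes with RGC_immunopanned_P14 as the soma and 5972 with Eye_FACS_P14. Replicate 1 of RGC_immunopanned_P14 stood apart from its own group (mean correlation 0.181), and that soma was not tested without it.

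With no filter the counts were 3611 for TRAP against EU at P14, 335 for the ratio, 1154 for EU age, 418 for 8 weeks, and 833 for TRAP age. They were 1055 and 1563 for the chase, 1263 and 128 for the fmr1ko label in EU and FACS libraries, 581 for TRAP minus EU, 15 and 44 for SC against LGN and 1176 and 1060 for the eye cells. With all wild-type P14 SC libraries they were 1379 for TRAP against EU at P14, 18 for EU age, 0 for the chase against P14, 964 for sarm1ko, and 6 and 847 for the fmr1ko label in EU and TRAP libraries. With a replicate block they were 1448 for TRAP against EU at P10, 610 for EU age, 436 for the chase against P14, 4 and 0 for the fmr1ko label in EU and FACS libraries, 4 for TRAP minus EU and 80 and 20 for SC against LGN. With the length trend removed they were 1 for the ratio, 273 for the chase against P14, 421 and 2 for the fmr1ko label in EU and FACS libraries, 522 for EU minus FACS and 2 for SC against LGN in EU. The split of higher and lower calls was 1382 and 2369 for axonal against somal EU RNA. Without CT010467.1 and the mitochondrially encoded genes the chase against P14 had 82, and with RLE size factors SC against LGN in EU had 1. With all tested genes in place of those in the report, the Pearson coefficients were 0.725 for TRAP against EU at both ages, 0.028 for TRAP against EU with the chase, 0.235 for age in EU and TRAP, and −0.081 for the fmr1ko label in EU and FACS.

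Without 1 library the counts ran from 950 to 3850 for axonal against somal EU RNA, 727 to 4062 and 1162 to 2855 for TRAP against EU at P14 and P10, 0 to 214 for the ratio, 42 to 2160 for EU age, 0 to 3360 for 8 weeks, and 0 to 253 for TRAP age. They ran from 0 to 37 and 1 to 4227 for the chase against P10 and P14, and 2743 to 10336 for sarm1ko. Ranges were 0 to 3499, 0 to 348 and 0 to 1 for the fmr1ko label in EU, TRAP and FACS libraries, 40 to 1462 and 4 to 2755 for its interactions, 3 to 10 and 0 to 4 for SC against LGN, and 0 to 25 and 0 to 5013 for the eye cells. The Pearson coefficients ran from 0.52 to 0.718 for TRAP against EU at both ages, 0.082 to 0.288 for TRAP against EU with the chase, 0.233 to 0.482 for age, −0.092 to 0.075 for the fmr1ko label in EU and TRAP, −0.185 to −0.086 in EU and FACS, and 0.142 to 0.403 for SC against LGN. The log2 fold change of Fmr1 in TRAP libraries ran from −2.29 to 0.51.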

Other observations

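Glial and blood transcripts were also higher in EU RNA of SC than in EU RNA of immunopanned RGC. Of 15 astrocyte genes 7 were higher, and 8 were higher and 1 lower when adjusted over the list alone (median log2 fold change 3.33, adjusted p = 4.1e-06, adjusted p = 0.16 with an estimated correlation). Fgfr3, a growth factor receptor of astrocytes, had 90.7 ± 32.3 normalised CPM against no counts, at least 1710-fold higher. Of 9 oligodendrocyte precursor genes 5 were higher, and 6 when adjusted over the list alone (median log2 fold change 12.12, and 8.77 with genes at 0 set to their bound; adjusted p = 1.3e-08, adjusted p = 0.06 with an estimated correlation). The transcription factor Olig1 had 306 ± 37.4 against no counts, at least 5780-fold higher. Of 6 erythroid genes 4 were higher, and 6 when adjusted over the list alone (median log2 fold change 4.87, adjusted p = 0.00078, adjusted p = 0.33 with an estimated correlation). Whether these transcripts were labelled in the eye, labelled in SC or passed the capture without label was not tested.

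In the sarm1ko libraries, mitochondrial ribosomal protein genes were lower together with the other nuclear-encoded mitochondrial genes. Of 78 members 1 was higher and 42 lower, and 3 and 46 when adjusted over the list alone (median log2 fold change −1.27, adjusted p = 1e-07, adjusted p = 0.54 with an estimated correlation). Mrpl34 had 5.11 ± 1.2 against 54.3 ± 24.4 normalised CPM. Of 15 axon injury response genes 1 was higher and 7 lower, also when adjusted over the list alone (median log2 fold change −1.34, adjusted p = 0.018, adjusted p = 0.52 with an estimated correlation). Of 289 zinc finger Zfp genes 64 were higher and 34 lower, and 50 and 31 when adjusted over the list alone (median log2 fold change 0.86, adjusted p = 0.016, adjusted p = 0.58 with an estimated correlation). In TRAP libraries, genes of inhibitory neurons were lower in SC than in LGN, with 3 of 11 called when adjusted over the list alone (median log2 fold change −1.57, adjusted p = 0.0014, adjusted p = 0.28 with an estimated correlation). There the choroid plexus gene Ttr had 5.69 ± 3.05 against 772 ± 851 (adjusted p = 0.44).

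All tests in the paragraphs that follow were chosen after the results were seen. For those of a transcript length trend, the predicted outcome was stated before it was computed.

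Mitochondrially encoded transcripts were higher in the EU libraries labelled fmr1ko and in the sarm1ko libraries than in the 3 shared P14 libraries, with 9.58% of counts the lowest share of the 6. These shares count more genes than the 13 of the list, whose lowest sum in the 6 was 31120 CPM. Unusually low values of the shared P14 libraries are argued against, for SC at P14, by the SC libraries of the other code series. Their highest share was 2.51% and their highest sum over the 13 genes 19750 CPM. Some other wild-type EU libraries lay within the range of the 6 by that sum, such as LGN replicate 1 (48590 CPM) and chase replicate 1 (94250 CPM). Others, such as LGN replicate 2 (19840 CPM), lay below it. A large share of CT010467.1 is argued against by the highest share of the P14 libraries without it, 2.65%. A trend on transcript length is argued against by the medians of the 13 genes with the trend removed, log2 5.5 (5.33 before) for the fmr1ko label and 4.98 (4.59 before) for sarm1ko, with 12 and 13 genes still called. Differences in capture or preparation between the groups stay open, and so do the fmr1ko label, the sarm1ko genotype, axotomy and the chase as biological differences, none of which was tested apart. As a hypothesis, RNA without label may have passed the capture in differing amounts, which libraries from mice without EU would test.

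Replicate 3 of the 8-week EU libraries stood apart from replicates 1 and 2. A P14 library under the 8-week label stays open. Replicate 3 correlated at 0.851 with P14 replicates 3 to 5 and 0.616 with replicates 1 and 2. By group means it was nearest to P10 EU (0.806), replicates 1 and 2 to sarm1ko (0.869, 0.892). Its oligodendrocyte precursor genes (mean log2 CPM 4.959) lay below all 5 P14 libraries (lowest 5.555). A swap with 1 of the 3 P14 libraries stays open for the same reason: replicate 5 correlated with 8-week replicates 1 and 2 almost as much as with the other P14 libraries (difference −0.062), but its precursor genes (5.844) lay with P14. A trend on transcript length is argued against, since with it removed the difference in favour of P14 was 0.209. Variation between animals at 8 weeks was not tested.

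The 3 TRAP libraries labelled fmr1ko stood apart from each other and from wild-type TRAP libraries. In replicate 2, rod RNA as the smaller part of an SC library is argued against by myelin markers at 0.221% of the wild-type TRAP level. An eye-cell library under the TRAP label is a candidate explanation for replicate 2, since it correlated more with FACS eye libraries than with wild-type TRAP libraries by 0.413. For replicates 1 and 3, EU or total RNA in place of ribosome-bound RNA stays open, since both correlated slightly more with EU libraries labelled fmr1ko than with wild-type TRAP libraries (the lower difference was 0.026). An effect of the fmr1ko label on ribosome-bound RNA stays open for them as well and was not tested apart.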
